A study of Mus musculus with 30 samples.

How the data were processed

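Prefrontal cortex of C57BL/6J mice at postnatal day 40 was profiled by bulk RNA sequencing of stranded poly(A) libraries. The 30 libraries fall into 8 groups of 3 or 4 by Adnp genotype (heterozygous, HT, or wild type, WT), sex and treatment (vehicle, fluoxetine or lithium), and each library was placed in its group from its title. The labels give 1 batch for all libraries. They number the replicates of each group without saying whether each came from a separate mouse, so the p-values measure the spread between these libraries. Drug dose and duration, and the part of Adnp that the mutant allele lacks, are not given in the sources used here.

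The deposited values are a gene-level signal, with 18240 genes in 30 columns. The values themselves show gene counts divided by 1 size factor per library. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and genome build GRCm38 were used; the annotation release, the filters and the handling of strand are not given in the sources used here. Every deposited column was a whole multiple of 1 step, and 100% of the values came out as whole reads within 0.01, so the reads behind each library were recovered. In 2 columns that step lay within 0.5% of 1. The ratio of the size factors recomputed by the median of ratios to the deposited ones was 1.014 to 1.02 in all libraries. Libraries held 23771758 to 34307061 reads. Genes with a mean near 10 rest on few reads per library and are limited by counting. Intervals and floors cover counting error only.

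Ensembl identifiers were matched to GENCODE mouse release M21, which uses build GRCm38, and 18227 of them had a symbol; 13 did not. Coordinates are from that annotation, 1-based. Replicates were compared before averaging: over 42 pairs within groups the chi-square per degree of freedom was 4.83 to 32.4, so that all pairs differed by more than sampling noise and each library was counted once.

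Tests were run in R 4.3.3 with limma 3.58.1 (trend and robust moderation) on log2(normalized count + 1), for the 16824 genes with a mean of at least 10 over all libraries. All 30 libraries entered 1 fit with a mean per group, without covariates, which left 22 residual degrees of freedom. Sex-averaged comparisons are the mean of the female and male contrasts. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Since values were normalized counts and not raw counts, limma was the main test; edgeR 4.0.16 (quasi-likelihood) was run on the recovered reads as an alternative, and DESeq2 1.42.0 as a further one.

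Gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, each adjusted over 39 lists per comparison. The groups, the tests, the 39 lists, the rule for naming genes and most alternatives were fixed before the data were examined. A list of meiosis and germline genes, the DESeq2 fit, the fit with the striatal and olfactory bulb marker scores as covariates, the fit without both libraries of lowest summed normalized counts (HT lithium male 4 and HT vehicle female 1), and the resampling of whole-library residuals were added after the data had been seen. So were some list tests: fluoxetine against lithium within each sex, the block with an estimated correlation, the lithium comparisons without HT lithium male 4, and leaving out each library for the lists that held. Of the 39 lists, 6 were called in none of the comparisons within 1 genotype, between genotypes or within 1 sex: BAF subunits (lowest adjusted camera p 0.107), neurotrophins and their receptors (0.404), mitochondrially encoded transcripts (0.0605), inhibitory neuron (0.383), ependymal (0.0575) and thalamus and hypothalamus markers (0.141). Among the tests of a difference between the sexes, camera called the mitochondrially encoded transcripts for lithium (0.0329, adjusted p = 0.61 with an estimated correlation) and for the difference between the drugs (0.0123, adjusted p = 0.63), and both calls were lost.

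The genes named are Adnp, then for genotype, fluoxetine and lithium up to 10 higher and 10 lower genes with the largest fold change among those called, with a mean of at least 50 and the same sign in both sexes; predicted and unnamed genes, pseudogenes and the sex label genes were left out. For the other comparisons up to 4 called genes per direction with the smallest p were taken, and for called lists the 4 members with the smallest p. Gm20716, Dpm1, Tob1, Zfp36l1, Zfp36l2, Hhex, Drd2, Xdh and Per2 (between the drugs in females), Eomes and the members of the germline list were chosen after their values were seen. Single values were compared by permutation of the libraries, 2-sided, exact where the splits could be enumerated.

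On counts simulated from the libraries' own means for the genotype comparison over both sexes (16756 genes in the step), the fit recovered 62% of genes changed 1.25-fold, 86% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 9 false calls. For the genotype comparison in females it recovered 54%, 76%, 90% and 100% (6 false calls), and in males 40%, 68%, 84% and 95.8% (5 false calls). Each gene was simulated on its own, without the variation that genes share in these libraries, so false calls in the real data may be more.

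Replicate numbers, taken from the titles, are shared between groups, and the correlation of same-numbered libraries' deviations from their group means was checked. For HT and WT vehicle males all 3 pairs correlated (r of 0.17 to 0.28 across genes, which are not independent replicates). Only 1 of the 3 HT libraries correlated best with its own number, so a pairing there was taken as possible and is not shown. In the other comparisons at least 1 pair lay at or under 0.1. The library names number HT lithium females 2 and 3 as 3 and 4, so the titles pair these 2 libraries with others than the names do. The pairing by library name was tried as well, chosen after the data had been seen. The alternatives were another scaling, pseudocounts of 0.25 and 8, no filter or a mean of at least 50, a replicate block, array weights, moderation without the robust option, fits of only the groups compared, count tools, and leaving out each library in turn. No WT mice given either drug were analysed here, so that genotype by drug effects cannot be computed.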

Results

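Gene expression was measured in the prefrontal cortex of 40-day-old C57BL/6J mice, wild type (WT) or heterozygous (HT) for Adnp. Adnp encodes a homeodomain chromatin protein whose human counterpart is mutated in a form of syndromic autism. HT mice received vehicle (4 female and 3 male libraries), fluoxetine, a serotonin reuptake inhibitor (4 and 4), or lithium, a mood stabilizer (3 and 4). WT mice received vehicle (4 and 4). The design asks which transcripts differ by genotype and by treatment, in each sex. Libraries held 23771758 to 34307061 reads assigned to genes, and values below are normalized read counts. WT vehicle libraries held 26800833 to 34307061 reads and HT vehicle libraries 24696124 to 30028492.

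The targeted gene was examined first. Adnp lies on chromosome 2 at 168180986 to 168207112, minus strand (GRCm38). Its normalized count was 1847, 1994, 1703 and 1868 in WT vehicle females 1 to 4 and 2228, 1806, 1843 and 1899 in WT vehicle males 1 to 4. In HT vehicle females it was 2112, 2238, 2076 and 2250, and in HT vehicle males 2287, 2305 and 2491. Under fluoxetine it was 1886, 2114, 2009 and 2275 in HT females and 2115, 2376, 2206 and 2469 in HT males. Under lithium it was 2037, 2227 and 2229 in HT females and 1889, 2276, 2125 and 2324 in HT males. The count under the symbol Adnp was thus higher in HT vehicle (2251 ± 137, SD, n = 7) than in WT vehicle libraries (1898 ± 157, SD, n = 8). The log2 fold change was 0.26 (SE 0.0524, limma adjusted p = 0.00996), against the direction that the genotype label names. The part of the gene that the mutant allele lacks is not given in the labels, so this count alone does not check them.

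A further annotated gene, Gm20716 (168180986 to 168230364, same strand), spans Adnp and its neighbour Dpm1, which encodes a subunit of dolichol-phosphate mannose synthase (168209048 to 168230591). Of the 5288 exonic bases of Gm20716, 83.1% are also exonic in Adnp and 16.9% in Dpm1, with 0 of its own. Counts of these 3 genes share reads and are uncertain one by one. Gm20716 fell from 2417 ± 158 (SD, n = 8) in WT vehicle to 1412 ± 90.2 (SD, n = 7) in HT vehicle (log2 fold change -0.78, limma adjusted p = 1.16e-06). Dpm1 was higher in HT vehicle, 730.7 ± 41 against 555.7 ± 56.3 (log2 fold change 0.40, limma adjusted p = 5.75e-05). The sum of Adnp and Gm20716 was 3663 ± 93.5 (SD, n = 7) in HT vehicle and 4316 ± 75.2 (SD, n = 8) in WT vehicle. That is 84.9% of the WT level (exact permutation p = 0.00016, 2-sided, the smallest that the permutations can give). All 22 HT libraries had a summed count of 3404 to 3887, below the 8 WT libraries at 4226 to 4433, so the sum went with every genotype label. With Dpm1 added, the HT vehicle sum was lower by 9.81%. Under fluoxetine the sum was 99.4% of HT vehicle (exact permutation p = 0.74, 2-sided, n = 8 and 7) and under lithium 100% (exact permutation p = 0.92, 2-sided, n = 7 and 7), differences within the spread of the libraries.

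**Figure D1:**
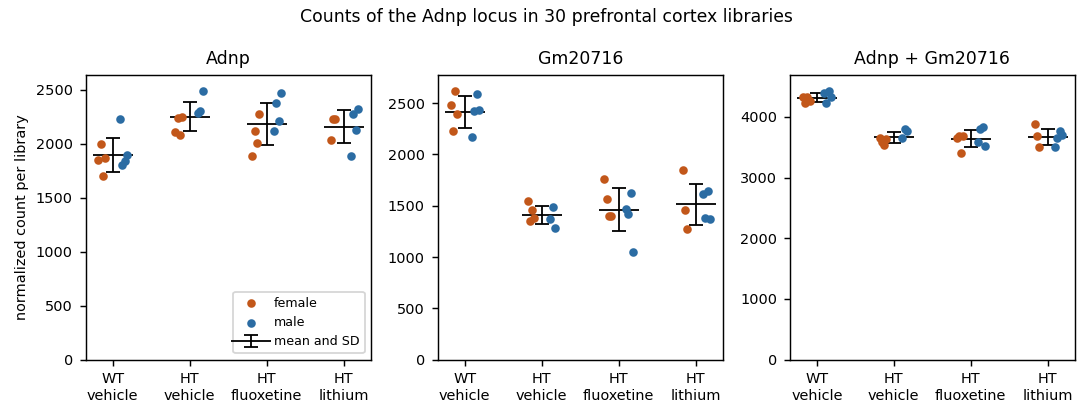
Normalized read counts (y axis, from 0) of Adnp, of Gm20716 and of their sum in each library of the 4 arms; points are libraries coloured by sex, and bars are the mean and SD of each arm. The summed count of all 22 HT libraries (3404 to 3887) lies below that of the 8 WT libraries (4226 to 4433).

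The comparison of HT with WT vehicle mice asks which transcripts differ by genotype without treatment. Rec8, the meiotic cohesin subunit, was 3.55-fold higher (229 ± 62.2, SD, n = 7, against 67.8 ± 28.3, n = 8). Rnf17, a tudor-domain gene of germ cells, was 2.58-fold higher (79.3 ± 8.33 against 30.5 ± 5.96), and Sycp2, of the synaptonemal complex, 2.43-fold (69.7 ± 20.3 against 27.9 ± 5.31). Sycp2 lies on the chromosome of Adnp, 10.2 Mb away. E2f2, a cell cycle transcription factor, was 2.57-fold higher (76.5 ± 9 against 29.5 ± 4.1). Col6a2, a collagen VI chain gene on chromosome 10 (76595762 to 76623630), had the smallest p. It was 1.99-fold higher, 1580 ± 119 (SD, n = 7) against 795 ± 84.1 (SD, n = 8; limma adjusted p = 1.09e-11). Xlr3a, of the X-linked lymphocyte-regulated family, was 2.76-fold higher, Stpg1, a sperm-tail repeat gene, 2.7-fold, and Ntn5, of the netrin family, 2.37-fold. The zinc finger genes Zfp992 and Zfp991 were 2.51-fold and 1.66-fold higher. Xlr3a and both zinc finger genes have near-identical copies, which makes their single values uncertain.

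Of the 10 named genes that fell, 6 were clustered protocadherins, neuronal adhesion genes whose variable exons join a shared constant end. Pcdhga7 was 416 ± 40 (SD, n = 7) against 594 ± 32.5 (SD, n = 8; log2 fold change -0.51, SE 0.06, limma adjusted p = 4.01e-06). Pcdha11 was 171 ± 23.6 against 252 ± 52.6, and Pcdhga9 327 ± 32.6 against 439 ± 56.3. Pcdhgb4, Pcdhga10 and Pcdhga6 had log2 fold changes of -0.38, -0.33 and -0.27. Reads of the shared exons can be split between members, so the single protocadherin values are uncertain. Over the 57 tested protocadherins of the 3 clusters, 5 were called higher and 6 lower, and their summed count differed by -0.0098 on the log2 scale. The other 4 named genes were Ccnf, which encodes cyclin F (-0.32), Ccdc80, a secreted matrix-associated protein gene (-0.29), Acot2, a mitochondrial acyl-CoA thioesterase gene (-0.28), and Neu4, a sialidase gene (-0.21).

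Limma called 123 of 16824 genes between HT and WT vehicle mice, 105 higher and 18 lower. At an unadjusted p under 0.05 there were 1111, and edgeR called 123 and DESeq2 144. The genes called higher were low in expression, with a median mean count of 68.8 against 499 for all genes tested. In 31 genes, all among the 123, every one of the 22 HT libraries, drug-treated ones included, lay on 1 side of the 8 WT libraries, where chance gives 3.4e-05% of genes. Some calls lay near the threshold. Leaving out 1 library ended the calls of Stpg1 and Pcdhga6 for 6 of 15 libraries each, Pcdhga10 for 5, Pcdha11 for 9, Ccnf and Acot2 for 10, Pcdhgb4 for 11 and Neu4 for 12. The highest limma adjusted p was 0.102 for Pcdha11, 0.101 for Pcdhgb4 and 0.118 for Acot2 without HT vehicle male 1, and 0.147 for Neu4 without male 3. Without male 2 it was 0.0786 for Stpg1, 0.0974 for Pcdhga10, 0.169 for Ccnf and 0.115 for Pcdhga6. With 1 library left out the log2 fold changes of these genes were 76.5% to 119% of the reported ones, the lowest for Ccnf (-0.25, without HT vehicle male 2). Neu4 was also not called by edgeR (adjusted p = 0.0515) or DESeq2 (0.0657). With the replicate number as a block, which may pair the vehicle males of this comparison, Neu4 (log2 fold change -0.21 in either fit, limma adjusted p = 0.0853) and Pcdhgb4 (-0.36 beside -0.38, adjusted p = 0.0566) were not called. With only the vehicle groups in the fit, Xlr3a, Pcdha11, Ccnf, Acot2, Pcdhga6 and Neu4 were not called (limma adjusted p of 0.0577, 0.101, 0.116, 0.158, 0.0557 and 0.147), while the group means are the same in that fit.

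Of 39 gene lists, camera called 6 between genotypes. Extracellular matrix and collagen genes were shifted upward (25 of 29 positive, median log2 fold change 0.15, camera adjusted p = 4.99e-06, adjusted p = 0.93 with an estimated correlation). Only Col6a2 of them was called over all genes, and 3 were adjusted over the list alone. Col6a1, which encodes another collagen VI chain, was 5950 ± 958 against 4310 ± 964 (limma adjusted p = 0.204). Cytosolic ribosomal protein genes were shifted by a median of 0.052 (74 of 83 positive, camera adjusted p = 1.17e-06, adjusted p = 0.93 with an estimated correlation), with 0 called and 1 adjusted over the list alone. Presynaptic vesicle genes (median -0.052, camera adjusted p = 0.00476) and excitatory synapse genes (median -0.035, 0.0165) were shifted downward (adjusted p = 0.93 each with an estimated correlation), with 0 called and 0 adjusted over the list alone in each. Oligodendrocyte precursor genes were shifted downward (median -0.067, camera adjusted p = 0.0331, adjusted p = 0.93 with an estimated correlation, and camera 0.0775 with the replicate block), with 2 called and 2 adjusted over the list alone, Neu4 and Pdgfra. Pdgfra, the growth factor receptor that marks these cells, was 1440 ± 55.1 against 1630 ± 81.6 (log2 fold change -0.18, limma adjusted p = 0.0303). Its call was lost for 10 of 15 libraries left out (up to 0.113, without HT vehicle male 2). Adnp and its partners of the ChAHP chromatin complex were called upward (median 0.05, camera adjusted p = 0.0165, adjusted p = 0.84 with an estimated correlation), with 1 called, Adnp itself, and 2 adjusted over the list alone. The count of Adnp by symbol is uncertain, as it shares reads with Gm20716, and the list was not tested without it. Chd4, the remodeller of that complex, had a log2 fold change of 0.15 (limma adjusted p = 0.155). The block also made a camera call of excitatory neuron markers (0.0418, adjusted p = 0.9 with an estimated correlation). None of these list calls held with an estimated correlation. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 1.7e-07 for the matrix list. That test can be carried by 1 member such as Col6a2, and the list was not tested without it. Fry's directional test called 0 of the 39 lists.

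Drug-treated HT mice were compared with WT vehicle mice to see how much of the genotype difference was left. Col6a2 was 2.01-fold higher than in WT vehicle under either drug. E2f2 was 2.55-fold higher under fluoxetine and 2.66-fold under lithium, and Rnf17 2.68-fold and 2.72-fold. Slc6a19, an amino acid transporter gene, was 4.22-fold higher under fluoxetine and Best1, a chloride channel gene, 3.43-fold under lithium. Pcdhga7 was lower under either drug (log2 fold changes -0.45 and -0.52). Pcdha5 (-0.48), Ccdc80 (-0.42) and Lrrtm4, a synaptic adhesion gene (-0.25), were lower under fluoxetine, and Pcdha11 (-0.82), Pcdhga9 (-0.58) and Pcdhga10 (-0.52) under lithium. Limma called 251 genes for fluoxetine (209 higher, 42 lower) and 332 for lithium (235 and 97). The lithium count was 196 without HT lithium female 3, 220 without WT vehicle female 3 and 501 without HT lithium male 2.

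Of the 123 genotype calls, 105 were called again in the same direction in fluoxetine-treated and 98 in lithium-treated HT mice. All 123 kept their sign, with a median of 97.6% and 95.9% of the vehicle difference. These genes were chosen by the genotype call and both comparisons use the same WT libraries, so sign and size are kept in part by design. For fluoxetine 93 higher and 12 lower calls were shared, where independent lists would share 1.3 and 0.045. For lithium 83 and 15 were shared, against 1.5 and 0.1. Unchanged groups simulated against the WT libraries gave an overlap of 0 at most in 20 simulations. Groups without an effect would give few calls, so that 0 cannot show how much overlap the shared WT libraries bring to lists this long. The values for independent lists leave out the shared libraries too. Part of the excess may come from the shared WT libraries.

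**Figure D2:**
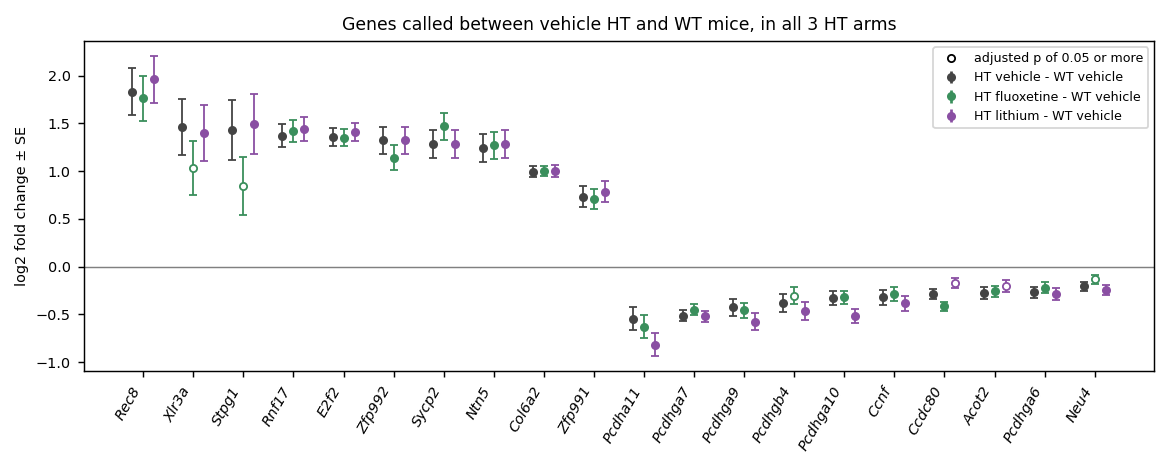
Log2 fold changes with their standard errors (y axis) of the 20 named genes called between HT and WT vehicle mice, for each of the 3 HT arms against WT vehicle; open symbols have an adjusted p of 0.05 or more. Col6a2 lies near 1 in all 3 arms, at 2.01-fold under each drug.

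Camera called 15 lists in fluoxetine-treated and 16 in lithium-treated HT mice against WT vehicle, and 0 held with an estimated correlation in either. Of the immediate early genes, 16 were called higher under fluoxetine, and 23 higher and 1 lower were adjusted over the list alone (camera adjusted p = 3.48e-24, adjusted p = 0.056 with an estimated correlation). Under lithium 13 were called, and 22 higher and 1 lower adjusted over the list alone (9.63e-20, adjusted p = 0.13 with an estimated correlation, and 0.043 without HT lithium male 4, a test chosen after the data had been seen). Matrix genes had 2 called in each, and 3 and 7 adjusted over the list alone (1.22e-06 and 1.19e-07, adjusted p = 0.48 and 0.44 with an estimated correlation). Oligodendrocyte precursor genes had 2 called lower under lithium, and 1 higher and 6 lower adjusted over the list alone (median -0.14, 0.00524, adjusted p = 0.44 with an estimated correlation). Olfactory bulb (median 1.2, 0.00524, adjusted p = 0.49) and meningeal fibroblast markers (0.44, 1.16e-05, adjusted p = 0.44) stood apart under lithium, with 0 called in each and 0 and 6 adjusted over the list alone. Excitatory neuron markers were shifted by -0.15 (0.00781, adjusted p = 0.49) and inhibitory synapse genes by -0.048 (0.0217, adjusted p = 0.44), with 0 called and 0 adjusted over the list alone. The excitatory neuron markers were not called without HT lithium male 4 (camera adjusted p = 0.0664).

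The comparison of fluoxetine with vehicle in HT mice asks which transcripts differ with the drug on the mutant background. Activity-dependent genes were higher under fluoxetine than under vehicle. Npas4, a neuronal activity-dependent transcription factor, was 2.02-fold higher than in HT vehicle (1420 ± 90.2, SD, n = 8, against 737 ± 179, n = 7; log2 fold change 1.01, SE 0.101, limma adjusted p = 5.26e-06). Fos and Fosb, of the AP-1 family, were 1.72-fold (1840 ± 159 against 1090 ± 155) and 1.88-fold higher (965 ± 201 against 520 ± 99.7). Btg2, of an antiproliferative family, was 1.74-fold higher (1120 ± 159 against 657 ± 129), the zinc finger gene Egr4 1.45-fold (1390 ± 154 against 955 ± 75.9) and the orphan nuclear receptor gene Nr4a1 1.33-fold (4980 ± 426 against 3770 ± 394). In WT vehicle libraries Npas4 was at 799 ± 127 and Fos at 1070 ± 108 (n = 8). These 6 were all the calls by limma, with 0 lower. There were 442 genes with an unadjusted p under 0.05, edgeR called 5 and DESeq2 12.

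The fluoxetine calls of Npas4, Fos and Btg2 stood with each library left out in turn. Those of Fosb, Egr4 and Nr4a1 were lost for 12, 10 and 14 of 15 libraries, at limma adjusted p of up to 0.164, 0.164 and 0.204, each without HT vehicle male 2, while their log2 fold changes stayed at 91.4% to 108% of the reported ones. Nr4a1 was also not called by edgeR (adjusted p = 0.0518). With the marker covariates described below it had a log2 fold change of 0.411 (SE 0.0824) beside 0.414 (SE 0.0779) as reported, and was not called as the standard error widened (limma adjusted p = 0.062). Egr4 was not called without HT lithium male 4 and HT vehicle female 1 together (0.52 beside 0.54 as reported, adjusted p = 0.06). The count of calls was 3 without fluoxetine female 2 or 4, fluoxetine male 2 or 4, HT vehicle female 2 or 4, or HT vehicle male 1 or 2.

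All 33 immediate early genes tested had a positive log2 fold change under fluoxetine (median 0.34). Of these, 6 were called over all genes and 23 adjusted over the list alone. It was the only list of the 10 called by camera (adjusted p = 1.23e-63) that held (adjusted p = 0.00022 with an estimated correlation, fry 0.00047), also with each library left out in turn (up to 0.002). Genes induced by glucocorticoids were shifted upward (median 0.066, camera adjusted p = 2.69e-05, adjusted p = 0.13 with an estimated correlation), with 0 called and 1 adjusted over the list alone. Circadian clock genes were shifted by 0.065 (2.69e-05, adjusted p = 0.13 with an estimated correlation; 0 called, 2 adjusted over the list alone) and interferon response genes by 0.14 (5.55e-07, adjusted p = 0.66; 0 and 0). Cholesterol synthesis genes were shifted by -0.05 (0.000316, adjusted p = 0.9; 0 and 0), cytoskeleton genes by -0.025 (0.00318, adjusted p = 0.9; 0 and 0) and the Adnp complex by -0.043 (0.0294, adjusted p = 0.33; 0 and 0). Markers of other cells moved as well, meningeal fibroblasts by 0.19 (0.00324, adjusted p = 0.9; 0 and 0) and myelinating oligodendrocytes by -0.19 (0.00516, adjusted p = 0.92; 0 and 0). The list of Y-linked genes and Xist was called too (0.000316, adjusted p = 0.059; 0 and 1). Fluoxetine females 1, 2 and 4 held 8, 5 and 11 reads of 4 Y-linked genes, 0.21%, 0.13% and 0.27% of the male level, against 0 in every other female library.

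The same comparison was made for lithium in HT mice. Npas4 was 2.31-fold higher (1710 ± 405, SD, n = 7, against 737 ± 179, n = 7; log2 fold change 1.21, SE 0.105, limma adjusted p = 2.78e-07). Btg2 was 2.05-fold higher (1340 ± 262 against 657 ± 129), Fosb 1.89-fold (1060 ± 397 against 520 ± 99.7) and Fos 1.87-fold (2120 ± 550 against 1090 ± 155). Ccn1, a matricellular protein gene, was at 363 ± 114 against 172 ± 16.8, and Egr2, a zinc finger transcription factor, at 734 ± 239 against 409 ± 57.6. Ier2 (1.57-fold), Nr4a1 (1.45-fold), Junb, of the AP-1 family (1.44-fold), and Dusp1, a MAP kinase phosphatase gene (1.43-fold), were also called higher. Limma called 15 genes, with 0 lower. There were 962 with an unadjusted p under 0.05, edgeR called 15 and DESeq2 18. The other 5, chosen after their values were seen, included Tob1 (log2 fold change 0.38), of the family of Btg2, the mRNA decay factors Zfp36l1 (0.34) and Zfp36l2 (0.36), and Hhex, a homeobox gene (0.67).

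The lithium libraries differed among themselves. The mean log2 level of the immediate early genes was 10.39, 9.771 and 9.868 in HT lithium females 1, 2 and 3 and 10.23, 10.36, 10.37 and 10.2 in males 1 to 4. Females 2 and 3 thus lay among the HT vehicle libraries, which ran from 9.672 to 9.893, while the 8 fluoxetine libraries ran from 10.01 to 10.21. Without HT lithium female 1 there were 8 lithium calls and without HT lithium male 3 there were 9. The calls of Ccn1, Fosb, Egr2 and Junb were lost for 6, 7, 8 and 3 of 14 libraries left out. The limma adjusted p was up to 0.0843 for Ccn1 without HT lithium female 1, and up to 0.0837, 0.0958 and 0.0931 for the other 3 without HT vehicle male 2. Their log2 fold changes ranged from 77.1% to 115% of the reported ones, each lowest without HT lithium female 1. With only the groups compared in the fit, limma called 5 genes, and Ccn1, Fosb, Egr2, Nr4a1, Junb and Dusp1 were not among them (adjusted p of 0.131, 0.359, 0.728, 0.132, 0.208 and 0.0548), at unchanged group means. With the marker covariates Egr2 had a log2 fold change of 0.79 (SE 0.156) beside 0.76 (SE 0.142) as reported, and was not called as the standard error widened (limma adjusted p = 0.0509).

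**Figure D3:**
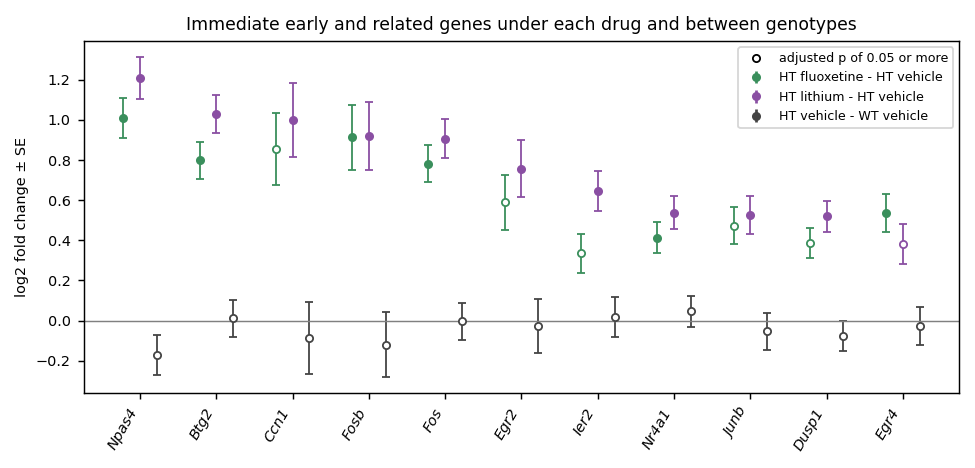
Log2 fold changes with standard errors (y axis) of the genes named for either drug, for fluoxetine and lithium against HT vehicle and for HT against WT vehicle; open symbols have an adjusted p of 0.05 or more. Npas4 is at 1.01 under fluoxetine and 1.21 under lithium, and at -0.17 between genotypes.

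Of the 33 immediate early genes, 31 were positive under lithium (median 0.35). There were 9 called over all genes and 22 adjusted over the list alone (camera adjusted p = 2.79e-41, adjusted p = 0.0036 with an estimated correlation, fry 0.00027). The list also held with each library left out in turn (up to 0.029, without HT vehicle male 2). The other 12 lists called by camera were lost with an estimated correlation. Wnt/beta-catenin target genes were shifted upward (17 of 19 positive, median 0.13, camera adjusted p = 0.000117, adjusted p = 0.45 with an estimated correlation), with 0 called and 1 adjusted over the list alone. Of these, the Wnt receptor gene Fzd7 had a log2 fold change of 0.48 (limma adjusted p = 0.535) and Axin2, a feedback inhibitor of the pathway, 0.11 (0.794). Interferon response genes were positive in 31 of 31 (median 0.23, 1.78e-11, adjusted p = 0.45; 0 called, 0 adjusted over the list alone). Excitatory synapse genes (median -0.052, 0.00231, adjusted p = 0.6), presynaptic genes (-0.058, 0.000623, adjusted p = 0.71) and voltage-gated ion channels (-0.055, 0.00148, adjusted p = 0.48) were shifted downward, each with 0 called and 0 adjusted over the list alone. Glucocorticoid-induced genes were shifted by -0.078 (0.00395, adjusted p = 0.48; 0 called, 1 adjusted over the list alone). Cytoskeleton genes were shifted by -0.057 (0.000934, adjusted p = 0.71) and matrix genes by 0.11 (0.0224, adjusted p = 0.73), each with 0 called and 0 adjusted over the list alone. Markers of neighbouring tissue moved with lithium. Striatal medium spiny neuron markers were shifted by -0.67 (0.000934, adjusted p = 0.71 with an estimated correlation), olfactory bulb markers by 0.92 (0.0189, adjusted p = 0.72) and meningeal fibroblast markers by 0.44 (3.84e-09, adjusted p = 0.45). Endothelial markers were shifted by 0.084 (0.0224, adjusted p = 0.71). None of their members was called by limma or adjusted over the list alone.

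HT lithium male 4 stood apart from the other lithium libraries in some of these lists. Its mean log2 level of the interferon response genes was 7.771, against 7.035 to 7.195 in the other 6, and that of the meningeal fibroblast markers 9.821, against 8.355 to 9.046. The lithium comparisons of lists were run again without it, chosen after the data had been seen. Interferon response genes then had a median of 0.13 and meningeal markers of 0.33, and both were still called by camera (adjusted p = 7.77e-07 each, adjusted p = 0.52 each with an estimated correlation). Excitatory synapse, presynaptic and cytoskeleton genes (camera adjusted p = 0.121 each), matrix genes (0.457), endothelial markers (0.0685) and olfactory bulb markers (0.115) were no longer called. Striatal markers (0.000538, adjusted p = 0.94 with an estimated correlation) still were.

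These tissue markers varied widely between libraries of 1 group. Drd2, a dopamine receptor gene of striatal neurons, ranged from 14.6 to 1200 over the 30 libraries and Eomes, a transcription factor gene of olfactory bulb projection neurons, from 3.43 to 976. The first component of the residuals held 26.1% of their variance and followed the striatal (r = 0.83) and olfactory (r = -0.82) marker scores. With both scores as covariates, a fit chosen after the data had been seen, 10 immediate early genes were called under fluoxetine and 9 under lithium. Without HT lithium male 4 and HT vehicle female 1, likewise chosen afterwards, the numbers were 5 and 9.

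**Figure D4:**
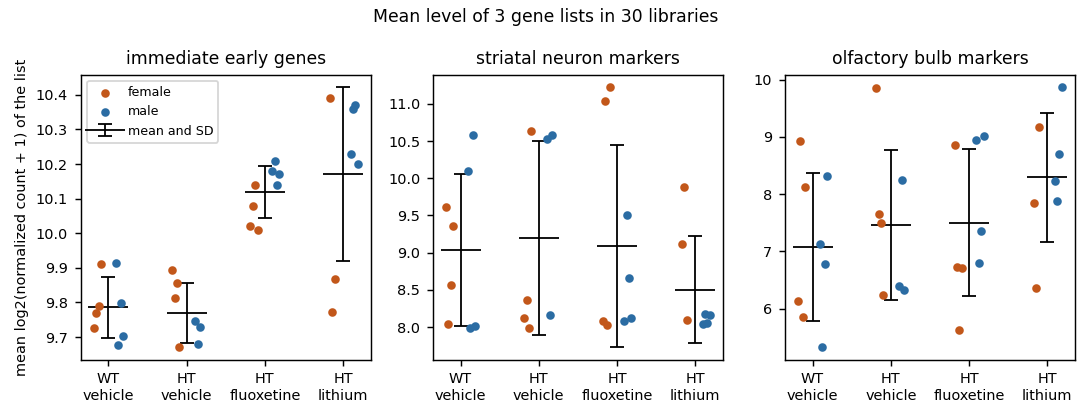
Mean log2(normalized count + 1) of the immediate early genes, of the striatal neuron markers and of the olfactory bulb markers in each library (y axes differ and do not start at 0); points are libraries coloured by sex, bars are the mean and SD of each arm. HT lithium females 2 and 3 (9.771 and 9.868) lie at the level of the vehicle libraries for immediate early genes, and both marker lists spread widely within every arm.

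The drugs shared 5 of the 6 fluoxetine calls, Npas4, Fos, Fosb, Btg2 and Nr4a1. Independent lists would share 0.0053, and unchanged groups simulated against the same HT vehicle libraries shared 0 at most. Neither value shows how much overlap the shared vehicle libraries bring, since groups without an effect would give few calls. Part of the overlap may come from the shared vehicle libraries. Directly compared, limma called 0 genes between fluoxetine and lithium in HT mice. There were 1154 with an unadjusted p under 0.05, edgeR called 0 and DESeq2 14, and limma called 4 without HT lithium female 1. Averaged over the sexes, glucocorticoid-induced genes were higher under fluoxetine than under lithium as a group (18 of 19 positive, median 0.16, camera adjusted p = 2.44e-10, adjusted p = 0.028 with an estimated correlation, fry 0.0083), with 0 called over all genes and 8 adjusted over the list alone. Among them Tsc22d3, a glucocorticoid-induced leucine zipper gene, was at 1580 ± 171 (SD, n = 8) under fluoxetine and 1340 ± 158 (SD, n = 7) under lithium (limma adjusted p = 0.209). Fkbp5, a chaperone of the glucocorticoid receptor, was at a ratio of 1.16 (0.474). The list was lost without HT fluoxetine female 1 (adjusted p = 0.13 with an estimated correlation) or female 2 (0.051), HT lithium female 2 (0.12) or female 3 (0.081), or HT lithium male 2 (0.12) or male 3 (0.054).

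The drugs were also compared by list within each sex, chosen after the data had been seen. Camera called 6 lists in females, of which only the glucocorticoid-induced genes held with an estimated correlation, and 14 in males, of which 0 held. In females the mean log2 level of the glucocorticoid-induced genes was 9.34 ± 0.108 (SD, n = 4) under fluoxetine and 8.99 ± 0.0652 (SD, n = 3) under lithium. There 18 of 19 were higher under fluoxetine (median 0.22, camera adjusted p = 4.02e-16, adjusted p = 0.0026 with an estimated correlation, fry 0.00052), and the list held with each library left out (up to 0.03, without HT lithium female 3). Xdh, the xanthine dehydrogenase gene, was the 1 member called (log2 fold change 0.97, limma adjusted p = 0.0272), and 10 were adjusted over the list alone. Other lists moved in the same females and were lost. Clock genes were positive in 16 of 19 (median 0.14, camera adjusted p = 6.45e-06, adjusted p = 0.09 with an estimated correlation). Of these 1 was called, the period gene Per2 (log2 fold change 0.68, limma adjusted p = 0.0272), and 1 adjusted over the list alone. The Y-linked genes and Xist were positive in 5 of 5 (median 0.88, camera adjusted p = 0.000539, adjusted p = 0.058 with an estimated correlation, fry 0.022; 0 called, 3 adjusted over the list alone). Red blood cell markers were negative in all 6 (median -0.44, 0.00649, adjusted p = 0.87 with an estimated correlation). Cholesterol synthesis (-0.083, 0.00434, adjusted p = 0.91) and cytoskeleton genes (-0.042, 0.0317, adjusted p = 0.91) were shifted downward, and these 3 lists had 0 called and 0 adjusted over the list alone. Striatal markers were positive in 12 of 12 (median 0.58) and olfactory bulb markers in 2 of 9 (median -1), and neither was called (camera adjusted p = 0.0859 and 0.0986).

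In males the level of the glucocorticoid-induced genes was 9.12 ± 0.128 (SD, n = 4) under fluoxetine and 9.12 ± 0.11 (SD, n = 4) under lithium, with 12 of 19 positive. The list was not called there (median 0.029, camera adjusted p = 0.435, adjusted p = 0.81 with an estimated correlation; 0 called, 0 adjusted over the list alone). Camera called the difference between the sexes (adjusted p = 2.37e-08), and it was lost (adjusted p = 0.071 with an estimated correlation), so the sexes are not shown to differ. The smallest camera p-values in males were those of presynaptic genes (median 0.12) and meningeal markers (-0.57; adjusted p = 1.06e-08 each, adjusted p = 0.42 each with an estimated correlation), with 0 called in each and 0 and 1 adjusted over the list alone.

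Between the drugs over both sexes, the other 11 lists called by camera were lost with an estimated correlation. They included clock genes (median 0.085, 5.09e-05, adjusted p = 0.18; 0 called, 1 adjusted over the list alone), Wnt targets (-0.077, 0.01, adjusted p = 0.69; 0 and 0) and pericyte markers (-0.11, 0.031, adjusted p = 0.69; 0 and 0). Striatal (0.52, 0.0139, adjusted p = 0.83), olfactory bulb (-0.95, 0.0165, adjusted p = 0.83) and meningeal markers (-0.25, 0.00112, adjusted p = 0.74) moved in the same comparison, with 0 called and 0 adjusted over the list alone. Without HT lithium male 4, Wnt targets (camera adjusted p = 0.116), pericyte (0.113), meningeal (0.0846) and olfactory bulb markers (0.116) were not called. Interferon response (0.858), excitatory synapse (0.519) and presynaptic genes (0.475) were not either. Cholesterol synthesis genes then were (median -0.071, 0.00248, adjusted p = 0.92 with an estimated correlation).

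To set the drug differences beside the genotype difference, their fold changes over all 16824 genes were correlated. HT vehicle libraries were first divided so that the comparisons shared none (36 divisions; the correlation is across genes, which are not independent replicates). The mean correlation with genotype was 0.16 for fluoxetine and 0.12 for lithium, and 0.019 between the drugs. When whole-library residuals were resampled without any effect, it ranged from -0.45 to 0.39, -0.49 to 0.39 and -0.37 to 0.43, so that the 3 values lie within chance. Without HT vehicle male 2 they were 0.0029, -0.08 and 0.24. With shared vehicle libraries the correlations were -0.28, -0.21 and 0.52. Noise simulated for each gene on its own, without any effect, gave -0.54, -0.52 and 0.52, but leaves out the variation that genes share. Resampled whole-library residuals gave -0.8 to 0.053, -0.84 to -0.058 and -0.053 to 0.84, so these values lie within chance too. The covariances were -0.0067, -0.0069 and 0.014 beside values of -0.014, -0.014 and 0.014 in the simulated noise. Limma called 0 of the 123 genotype genes in either drug comparison, and 0 adjusted over these genes alone (over all genes, 442 and 962 had an unadjusted p under 0.05, edgeR called 5 and 15, and DESeq2 12 and 18).

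The genotype comparison was repeated within each sex. In females limma called 43 genes (40 higher, 3 lower), led by Col6a2 (2.08-fold), E2f2 (2.39-fold), Slc6a19 (4.3-fold) and Prss50, a testis serine protease gene (3.45-fold), with Pcdhga7 (log2 fold change -0.56) and Ccdc80 (-0.32) lower. In males 38 were called (36 and 2), led by Col6a2 (1.91-fold), E2f2 (2.77-fold), Rnf17 (2.7-fold) and Best1 (3.43-fold), with Pcdhga7 lower (-0.47). Of these, 24 higher and 2 lower genes were called in both sexes, where independent lists would share 0.086 and 0.00036. The Ccdc80 call in females was lost for 6 of 8 libraries left out (up to limma adjusted p = 0.256 at a log2 fold change of -0.28, without WT vehicle female 4). The Pcdhga7 call in males was lost without HT vehicle male 3 (log2 fold change -0.34, adjusted p = 0.229). With only the groups compared in the fit, Prss50 (0.0626), Ccdc80 (0.676) and, in males, Pcdhga7 (0.198) were not called. Calls in females numbered 28 without WT vehicle female 3. In males they numbered 19 without HT vehicle male 1 or WT vehicle male 4, 22 without HT vehicle male 2, 20 without HT vehicle male 3 and 25 without WT vehicle male 2. Camera called 8 lists in females and 6 in males, and 0 held (lowest adjusted p = 0.92 and 0.83 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were shifted by 0.05 in males (camera adjusted p = 0.00018, adjusted p = 0.9 with an estimated correlation; 0 called, 0 adjusted over the list alone). With the replicate number as a block, which may pair the libraries in males, 3 more lists were called there, presynaptic genes (0.0139, from 0.0952), ion channels (0.021, from 0.082) and striatal markers (0.0325, from 0.0825). All 3 were lost in the blocked fit, at an adjusted p = 0.83 each with an estimated correlation. With the block numbered by library names, chosen after the data had been seen, striatal markers were not called (0.0602) and immediate early genes were (0.038, adjusted p = 0.81 with an estimated correlation).

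In males Npas4 was 2.51-fold, Btg2 2.19-fold and Fos 2.06-fold higher under fluoxetine than under vehicle, the 3 genes called by limma (edgeR 3, DESeq2 10). Under lithium 13 genes were called in males, among them Npas4 (3.25-fold), Btg2 (2.55-fold), Fos (2.53-fold) and Nr4a1 (1.68-fold), and 8 were called without HT vehicle male 1 or male 3. In females limma called 0 genes under either drug (648 and 597 at an unadjusted p under 0.05; edgeR 0 and 0, DESeq2 2 and 3), with Npas4 at 1.62-fold and 1.65-fold (adjusted p = 0.258 and 0.302). In females 1 gene was called for fluoxetine without HT fluoxetine female 3 and 4 for lithium without HT lithium female 2. Immediate early genes held in males (adjusted p = 0.0059 with an estimated correlation for fluoxetine, 3 called and 19 adjusted over the list alone; adjusted p = 0.026 for lithium, 8 and 23). With single libraries left out, a test chosen after the data had been seen, the list was lost for fluoxetine without HT vehicle male 2 (adjusted p = 0.12 with an estimated correlation). For lithium it was lost without that library (adjusted p = 0.2) and without HT lithium male 2 (adjusted p = 0.17). In females the list did not hold (adjusted p = 0.08 with an estimated correlation, 0 and 10; adjusted p = 0.57, 0 and 9). The difference between the sexes was tested directly. For the immediate early genes as a list, camera called it (adjusted p = 0.000102 for fluoxetine and 2.74e-09 for lithium), and it was lost (adjusted p = 0.51 and 0.59 with an estimated correlation), so the sexes are not shown to differ. Gene by gene, limma called 0 genes by interaction for genotype, fluoxetine or lithium (345, 1002 and 1684 at an unadjusted p under 0.05; edgeR 0, 0 and 0; DESeq2 0, 1 and 0). For lithium 2 were called without HT lithium female 1 and 1 without HT vehicle female 4.

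Tissue markers moved within the sexes too. In lithium-treated males meningeal (median 0.73, camera adjusted p = 2.98e-08), olfactory bulb (1.9, 0.00387) and striatal markers (-1.6, 6.98e-06) moved with the immediate early genes, with 0 called and 9, 0 and 0 adjusted over the list alone. All 3 were lost (adjusted p = 0.45, 0.57 and 0.57 with an estimated correlation). Without HT lithium male 4, whose meningeal level of 9.821 was the highest in lithium mice, their medians were 0.44, 1.5 and -1.5 (camera adjusted p = 4.81e-06, 0.0311 and 1.14e-06; adjusted p = 0.64, 0.65 and 0.64 with an estimated correlation). The interferon median in these males went from 0.38 to 0.19 (camera adjusted p = 1.91e-10 and 9.07e-06; adjusted p = 0.45 and 0.64 with an estimated correlation). The calls of matrix (0.0625), heat shock (0.0625) and cholesterol synthesis genes (0.218) ended. Those of glucocorticoid-induced genes (0.0224), mitochondrially encoded transcripts (0.0367), oligodendrocyte precursor (0.0489) and red blood cell markers (0.0416) appeared, each lost (adjusted p = 0.64, 0.65, 0.65 and 0.65 with an estimated correlation). In fluoxetine-treated males striatal (-1.1, 1.51e-05) and myelin markers (-0.47, 1.45e-05) moved, each with 0 called and 0 adjusted over the list alone (adjusted p = 0.7 in each with an estimated correlation). In fluoxetine-treated females glucocorticoid-induced genes were higher than in vehicle females as a group (18 of 19 positive, median 0.21, camera adjusted p = 9.88e-14, adjusted p = 0.0073 with an estimated correlation, fry 0.0077; 0 called, 6 adjusted over the list alone). The list was lost without HT fluoxetine female 1 (adjusted p = 0.17 with an estimated correlation). The difference from males had an adjusted p = 0.13 with an estimated correlation. The list of Y-linked genes and Xist also held there (adjusted p = 0.017 with an estimated correlation; 0 called, 3 adjusted over the list alone), with the Y-linked reads given above. It was lost without HT fluoxetine female 1 (adjusted p = 0.34 with an estimated correlation) or HT vehicle female 4 (0.085). Striatal (0.84, 0.000713) and olfactory bulb markers (-0.93, 0.0188) moved in the same females, with 0 called and 0 adjusted over the list alone (adjusted p = 0.59 in each with an estimated correlation).

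Further lists were called by camera within 1 sex and lost with an estimated correlation, each with 0 called and 0 adjusted over the list alone. In fluoxetine-treated females choroid plexus markers were shifted by 0.39 (camera adjusted p = 0.044, adjusted p = 0.53 with an estimated correlation) and microglial markers by 0.073 (0.00749, adjusted p = 0.57). Endoplasmic reticulum stress genes were shifted by 0.03 (0.00749, adjusted p = 0.57), inositol metabolism genes by 0.053 (0.0404, adjusted p = 0.53) and autism risk genes by -0.021 (0.0404, adjusted p = 0.59). In lithium-treated females red blood cell markers were shifted by 0.48 (0.000149, adjusted p = 0.57) and heat shock genes by 0.057 (0.0497, adjusted p = 0.95). In lithium-treated males serotonin signalling genes were shifted by -0.11 (0.0497, adjusted p = 0.41) and astrocyte markers by 0.11 (0.0195, adjusted p = 0.57).

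Between WT vehicle males and females, limma called 19 genes (12 higher in males, 7 lower; edgeR 16, DESeq2 23). Xist, the X inactivation RNA, was at 17700 or more in every female library and at 53.6 or less in every male library, with the label given. Eif2s3x and Ddx3x, X-linked genes that escape inactivation, were lower in males (log2 fold changes -0.60 and -0.32). Ddit4, a stress-induced inhibitor of mTOR signalling, was 1.42-fold higher in males (limma adjusted p = 0.000755) and Sgk1, a kinase gene induced by glucocorticoids, 1.57-fold (0.00223). The count was 12 without WT vehicle female 1 or male 4.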

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

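The set of genes whose libraries were compared singly here was fixed after their results had been seen, and the tests of a sex difference by gene list were chosen after the data had been seen. Over 400 tests, each of 1 gene or the Adnp sum in 1 group or arm, Dixon's ratio flagged a single library 25 times. Chance flags about 1 in 20 tests, or 20 of these. The tests are not independent, since an arm holds its groups and some values were flagged in both. The count is thus close to chance, and no explanation was tested for any of them.

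Among the genotype genes, Zfp992 was at 15.42 in WT vehicle male 2 (29.13 to 31.73 in the other WT males, 29.13 to 41.23 in the other WT libraries), and Col6a2 at 784.8 in WT vehicle female 4 (727.3 to 732.4 in the other females). Zfp991 was at 208.3 in HT fluoxetine male 3 (150.3 to 156 in the other males, 132.9 to 157.6 in the arm) and at 197.9 in HT lithium male 4 (159.5 to 162.9). Pcdha11 was at 164.1 in WT vehicle female 2 (292 to 299.9). Pcdhga7 was at 381.8 in HT fluoxetine female 1 (477.8 to 484.2), 472.8 in HT lithium male 1 (395.8 to 402.6) and 591.2 in WT vehicle male 3 (569.7 to 573). Pcdhga6 was at 500.4 in HT vehicle female 1 (611.2 to 618.7), 668.7 in WT vehicle female 4 (723.5 to 733.4) and 609 in WT vehicle male 2 (686.6 to 701.4). Ccnf was at 135.8 in WT vehicle female 2 (157.5 to 172.4 in the other WT libraries), and Ccdc80 at 199.5 in HT fluoxetine female 1 (212.8 to 215.5). Neu4 was at 230.2 in HT lithium male 3 (237.3 to 237.5), 325.9 in WT vehicle male 1 (268.1 to 270 in the other males, 251 to 276.8 in the arm) and 283.4 in HT fluoxetine female 3 (238.2 to 257.3). Pdgfra was at 1220 in HT lithium female 1 (1460 to 1547).

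Among the other genes, Egr2 was at 476.5 in HT fluoxetine female 1 (583.1 to 599.1) and Junb at 1969 in HT vehicle female 1 (2234 to 2284). Ddx3x was at 7559 in HT fluoxetine male 3 (6918 to 7014) and Sgk1 at 1487 in WT vehicle female 4 (1300 to 1329). The sum of Adnp and Gm20716 was 3404 in HT fluoxetine female 3 (3647 to 3681 in the other females), still on the HT side of the WT range.

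Camera called 5 lists for a difference between the sexes in the genotype effect, 15 in the fluoxetine effect and 19 in the lithium effect, of 39 each, and 0 of these held with an estimated correlation. For the difference between the drugs it called 18 by sex, and 0 held. Values are given for the lists that held in at least 1 other comparison. Glucocorticoid-induced genes differed for genotype (camera adjusted p = 2.46e-07, adjusted p = 0.14 with an estimated correlation) and for fluoxetine (9.87e-08, adjusted p = 0.13), in each with a lower effect in males. Immediate early genes differed for fluoxetine (0.000102, adjusted p = 0.51) and lithium (2.74e-09, adjusted p = 0.59), in each with a higher effect in males. The list of Y-linked genes and Xist differed for fluoxetine (0.019, adjusted p = 0.51). Between fluoxetine and lithium these lists differed by sex too, at 2.37e-08 (adjusted p = 0.071 with an estimated correlation), 0.001 (adjusted p = 0.57) and 0.00759 (adjusted p = 0.32), in each with a lower value of fluoxetine against lithium in males.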

How the results depend on the processing

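The DESeq2 fits, the fits with the striatal and olfactory bulb scores as covariates and the fits without HT lithium male 4 and HT vehicle female 1 together were chosen after seeing the data, as were the list tests with the block and an estimated correlation, without HT lithium male 4, and with each library left out, and the block numbered by library names. Every call count kept within 1.5 times of the reported one under TMM rescaling, either pseudocount, no low-value filter, moderation without the robust option and edgeR. Of 158 values of named genes, 158 kept direction and call under TMM rescaling, under each pseudocount and without robust moderation. Leaving out 1 library gave 2074 such values, of which 1914 kept both, 146 lost the call, 6 gained one and 8 reversed. With only the groups compared 15 calls were lost and 1 gained. Except where a setting tests fewer genes or samples, the cause was not tested.

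With a mean of at least 50, which tests fewer genes, calls numbered 68 for genotype, 165 for fluoxetine-treated HT against WT, and 20 and 21 for genotype in females and males. With array weights they numbered 208 for genotype, 17 for fluoxetine, 4 between the drugs, 497 and 600 for fluoxetine- and lithium-treated HT against WT, 77 and 69 for genotype in females and males, 1 for lithium in females, 13 and 104 for fluoxetine and lithium in males, and 31 for sex. With only the groups compared, which uses fewer samples, they numbered 11 for fluoxetine, 5 for lithium, 208 for lithium-treated HT against WT, 11 and 12 for genotype in females and males, and 11 for fluoxetine in males. DESeq2 called 12 for fluoxetine, 14 between the drugs, 2 and 3 for fluoxetine and lithium in females, 10 and 43 in males, and 1 for fluoxetine by sex. With the covariates calls numbered 238 for genotype, 14 for fluoxetine, 9 between the drugs, 518 for fluoxetine-treated HT against WT, 98 and 76 for genotype in females and males, 1 for fluoxetine in females and 29 for sex. Without HT lithium male 4 and HT vehicle female 1 together they were 124 for genotype, 5 for fluoxetine and 14 for lithium. On the genotype-called genes alone the correlations with genotype were -0.12 for fluoxetine and -0.065 for lithium. These genes were chosen by the genotype call on the same HT vehicle libraries, which pushes both values below 0 without any drug effect. No values without an effect are given for this set, so the signs show no reversal by the drugs. List calls with an estimated correlation and with fry numbered 0 and 0 for genotype, 1 and 1 for fluoxetine, and 1 and 1 for lithium, and with the block and an estimated correlation 0, 1 and 1.

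With 1 library left out, calls ranged from 88 to 116 for genotype, 3 to 7 for fluoxetine, 8 to 16 for lithium and 0 to 4 between the drugs (4 without HT lithium female 1). They ranged from 176 to 268 for fluoxetine-treated and 196 to 501 for lithium-treated HT against WT (196 without HT lithium female 3, 501 without HT lithium male 2). For genotype they ranged from 28 (without WT vehicle female 3) to 43 in females and from 19 (without HT vehicle male 1 or WT vehicle male 4) to 31 in males. In females they were 0 to 1 for fluoxetine and 0 to 4 for lithium, in males 3 to 3 and 8 to 17. By sex they were 0 to 0 for genotype and fluoxetine and 0 to 2 for lithium, and for sex in WT 12 to 17. The correlations ranged from 0.0029 to 0.23, -0.08 to 0.22 and -0.13 to 0.24, and HT vehicle male 2 moved all 3. Of the lists that held with an estimated correlation, the immediate early genes stayed under 0.05 for both drugs over both sexes (adjusted p up to 0.002 and 0.029). Between the drugs the glucocorticoid-induced genes were lost for 6 of 15 libraries (up to 0.13) over both sexes and for 0 of 7 in females (up to 0.03). For fluoxetine in females they were lost for 1 of 8 (0.17) and the Y-linked genes with Xist for 2 (up to 0.34, both highest without HT fluoxetine female 1). In males the immediate early genes were lost for 1 of 7 under fluoxetine (0.12) and 2 under lithium (up to 0.2, both highest without HT vehicle male 2).

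Dpm1 was not called under either drug (log2 fold change 0.00653 and 0.00881), and its sign reversed under some settings. With 1 library left out it ranged from -0.0203 to 0.0325 for fluoxetine and from -0.00578 to 0.0348 for lithium, both highest without HT vehicle male 2. For fluoxetine it was -0.00592 with array weights, -0.0019 with the covariates, -0.00806 without HT lithium male 4 and HT vehicle female 1 together, and -0.0203, -0.00806, -0.0015, -0.00583 and -0.00709 without HT fluoxetine female 1 and HT vehicle female 1, female 4, male 1 and male 3. For lithium it was -0.0187 with the covariates, -0.00999 without both libraries, and -0.00578, -0.00355 and -0.00481 without HT vehicle female 1, male 1 and male 3.

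With the replicate block calls numbered 117 for genotype, 7 for fluoxetine, 14 for lithium, 0 between the drugs, 222 and 338 for the drug arms against WT, 39 and 32 for genotype in females and males, 0 and 0 for the drugs in females, 3 and 15 in males, 0 for each difference by sex and 16 for sex, and the correlations were 0.098, 0.093 and 0.046. Only the vehicle males met the check for pairing, and there 1 of 3 HT libraries correlated best with its own number. Elsewhere the lowest and highest correlation of same-numbered pairs was -0.34 and 0.15 for genotype in females, -0.11 and 0.45 for fluoxetine in females (3 of 4 libraries correlated best with their own number), -0.43 and 0.037 in males, -0.017 and 0.084 for lithium in females (-0.4 and -0.017 by the numbers in the library names, which are 3 and 4 for lithium females 2 and 3) and -0.2 and 0.037 in males. A block by those numbers kept every call count within 1.5 times (119 for genotype, 7 for fluoxetine, 15 for lithium, 272 for lithium-treated HT against WT), and of 158 values of named genes it kept 155, with 2 calls lost (Neu4, 0.0777, and Ccdc80 in females, 0.0506) and 1 gained. List calls under it numbered 6, 10 and 11 for genotype, fluoxetine and lithium. Outside the vehicle males a pairing was not assumed, although for fluoxetine in females 3 of 4 libraries correlated best with their own number. For genotype over both sexes, which includes the possibly paired vehicle males, Neu4 (adjusted p = 0.0853), Pcdhgb4 (0.0566) and the oligodendrocyte precursor list (0.0775) were not called with the block, and excitatory neuron markers were (0.0418, adjusted p = 0.9 with an estimated correlation). The block also made list calls of cholesterol synthesis for lithium-treated HT against WT (0.0459), myelin markers for lithium in females (0.0212), clock genes for fluoxetine in males (0.0297), and mitochondrially encoded transcripts (0.0224) and oligodendrocyte precursors (0.0372) for lithium in males. All 5 were lost (adjusted p = 0.72, 0.86, 0.71, 0.56 and 0.56 with an estimated correlation in the blocked fit). It ended those of endothelial and choroid plexus markers for fluoxetine in females (0.0509 each), glucocorticoid-induced (0.0526) and heat shock genes (0.0791) for lithium in females, and olfactory bulb markers for fluoxetine in males (0.163).

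Of the genes called higher between genotypes, 40% have a mean under 50, against 17.8% of all genes tested. How far depth limits the calls among low genes was not tested.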

Other observations

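The germline list, the genes named in the next 2 paragraphs, the comparison with WT vehicle as a test of low HT vehicle values, the edgeR comparison as a test of the log scale, the count around Adnp, the fits with marker covariates, and the tests of read division and of a mislabelled library were chosen after the results or the data were seen. Only the splits of the samples were set before.

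A list of meiosis and germline genes was examined in HT against WT vehicle mice. The list was written after genotype calls of this kind had been seen and holds called genes, so its test is not independent evidence. Of 60 genes listed, 34 were tested, 24 had a positive log2 fold change between HT and WT vehicle (median 0.32), and 11 were called higher with 0 lower (camera p = 3.12e-21, p = 7.7e-09 with an estimated correlation). Prss50, a serine protease gene of the testis, had a log2 fold change of 1.71, Spef2, a sperm flagellum gene, 1.35, and Xlr4b 2.03. Sycp3, Tdrd1 and Stag3 had values of 0.72, 0.66 and -0.39 and were not called (adjusted p = 0.424, 0.185 and 0.647). Against WT vehicle 26 were positive and 10 called in fluoxetine-treated HT mice (p = 3.3e-07 with an estimated correlation), and 28 and 10 in lithium-treated ones (p = 3.4e-07). Within HT mice limma's camera gave the list a p of 0.303 for fluoxetine and 0.595 for lithium.

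E230025N22Rik, an unnamed gene with a mean count of 13.4, had a log2 fold change of 3.56 between HT and WT vehicle. Slc6a19 and Best1, named above for the drug-treated arms, were at 1.95 and 1.68 in the same comparison. All 3 separated the 22 HT from the 8 WT libraries.

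Immediate early genes were higher under both drugs, by a mean of 0.355 (SE 0.0649) on the log2 scale for fluoxetine and 0.386 (SE 0.0674) for lithium. Against WT vehicle at least 93.7% of the difference was left (0.333 and 0.363, lower 95% bounds 0.203 and 0.229). The list did not hold there with an estimated correlation for either drug. With both marker scores as covariates at least 98.3% was left (lower 95% bounds 0.213 and 0.227). These bounds use 1 spread pooled over the 8 groups. The SD of the list level was 0.334 in HT lithium females (n = 3) and 0.106 or less in every other group, so the lithium bounds may be too high. For fluoxetine, values that happened to be low in HT vehicle argue poorly as the whole cause. A varying share of striatum and olfactory bulb in the dissection argues poorly there too. For lithium the bounds do not settle either. The way or time of day in which arms were handled and collected could raise these genes and was not tested, and HT lithium females 2 and 3 lay at the vehicle level. A response of HT cortex to the drugs stays a hypothesis, and without drug-treated WT mice its link to genotype cannot be computed.

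Genotype calls were mostly higher in HT and low in expression. With the striatal and olfactory scores as covariates 121 of the 123 were called again in the same direction, and edgeR on the recovered reads called 118 of them, which argues against dissection and against the log scale as the whole cause. Sequence around the targeted gene could bring linked differences, but only 4 calls lay within 20 Mb of Adnp, where 2.8 would be expected, which argues against it as the whole cause. Of these, 3 are Adnp, Gm20716 and Dpm1, and the other is Sycp2, 10.2 Mb away, for which a linked difference stays open. Among the chromosomes only 18 stood out, with 14 calls where 3.5 would be expected (Fisher test adjusted p = 0.00021). Pcdhga7 and Pcdhga11 lie on it, members of the clustered protocadherins, of which 5 were called higher and 6 lower of 57 tested. Reads divided between protocadherins make such single calls uncertain, while the Fisher test takes genes as independent. The excess was not tested without the protocadherins, so it does not show an effect of the chromosome at large. An effect of the genotype stays open with no mechanism tested, and deeper WT libraries, reads shared between copies and litter effects were not tested.

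Adnp rose by symbol while Gm20716 fell. A division of reads between these overlapping genes is a candidate explanation: over the 30 libraries their deviations from group means had r = -0.78 (permutation p = 2e-05; Spearman's rho -0.78, permutation p = 3e-05), and r = -0.77 without the 2 libraries farthest from the median. A library mislabelled for genotype is argued against, since 0 libraries had a summed count that reached the other genotype's range. The sum was alike in the HT arms, so it cannot show an exchange of treatment labels among them. A division between these 2 genes does not explain their lower sum in HT. A division with Dpm1 could account for a part. The HT vehicle sum was 3663 against 4316 in WT vehicle without Dpm1 (lower by 15.1%), and 4394 against 4871 with it (lower by 9.81%). The 2 percentages have different bases, so their difference overstates that part. Whether transcripts of the mutant allele are counted in the sum stays open.

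Other splits of the same libraries bear on chance. Of 100 splits drawn for each comparison over both sexes, only 1, the real one, gave as many calls for genotype (123, highest other 2), fluoxetine (6, highest other 1), lithium (15, highest other 5), fluoxetine-treated HT against WT (251, highest other 51) and lithium-treated HT against WT (332, highest other 54). Chance is thus an unlikely source of these counts but is not excluded, as 1 of 100 is the lowest share that these splits can give. Only the real one of 35 splits gave as many in each of genotype in females (43, highest other 1) and males (38, highest other 8), fluoxetine in males (3, highest other 0), lithium in males (13, highest other 4) and sex in WT (19, highest other 0). There 1 of 35 is the lowest share possible, which is a weaker bound. In vehicle males, where the numbers may pair the libraries, 8 splits part as many pairs as the real one, and the highest other of them gave 1. A count of 0 is reached by every split whatever the values, so the splits of such comparisons say nothing about chance. These were 100 of 100 between the drugs (highest other 4), 35 of 35 for fluoxetine and lithium in females (highest other 1185 and 1), and 100 of 100 for genotype, fluoxetine and lithium by sex (highest other 23, 3 and 13). The split with 1185 calls among the fluoxetine and vehicle females points to a structure of these samples that is not treatment, as do, on a smaller scale, the splits with 23 and 13. The splits with 51 and 54 calls mix WT and HT libraries, so such a structure and the genotype difference cannot be told apart in them.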
